A study of Mus musculus with 7 samples.

How the data were processed

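Total RNA of sorted mouse Paneth cells, the antimicrobial secretory cells at the base of small-intestinal crypts, was measured on 7 Affymetrix arrays, 1 array per sample. The labels call the samples biological replicates. They came from mice aged 4 months that were fed freely (ad libitum, n = 3) or received 60% of the ad libitum calories (n = 4) for 4 to 7 weeks. Cells were isolated by flow cytometry, and 10 ug of total RNA was labelled with biotin, per the labels' protocols.

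The deposited values are log2 expression values per transcript cluster, the array's gene-level probe set. They were made by the authors with Affymetrix Expression Console, per the submitters' processing notes. The algorithm, version, background correction and normalization are not given in the sources used here. The deposited log2 values ran from about 3 to 15 on each array, with array medians between 7.24 and 7.44, and were used without further scaling. The scale was inferred from this range. No detection call was used, so a level near the bottom of the range has no stated background. The number of arrays limits the precision.

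The table held 35556 transcript clusters. The platform annotation gave 1 gene symbol for 21789 of them and several symbols for 1621, and 12146 were unnamed here. Symbols were checked through gene identifiers against a RefSeq gene table of assembly GRCm38.p6, which changed 0 of them. Genes were named only from clusters with 1 symbol. For each of 19938 genes, the cluster with the highest mean over all arrays was kept. Genes with a mean below the 40th percentile of all clusters (6.79) were left out, which left 13409 genes. Of the 8 clusters that name an alpha-defensin (Defa) gene, 2 had 1 symbol. The others were left out, and probes of this family can bind near-identical copies, so their values are uncertain.

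The diets were compared with limma (version 3.58.1, R version 4.3.3) using lmFit and eBayes with an intensity trend, no covariates, and Benjamini-Hochberg adjustment over all genes tested. Genes with an adjusted p below 0.05 were called. Differences are calorie restricted minus ad libitum on the log2 scale, with the standard error (SE) of the moderated fit and 95% intervals where given. Bst1 was also put to an exact two-sided permutation test over all 35 splits of the arrays into 4 and 3. On simulated arrays with the real gene means and spreads over 13409 genes, the fit recovered 99.0% of 100 genes changed by 2 log2 units and 76.0% of 100 changed by 1, with 11 of 186 calls among unchanged genes. These simulated arrays had no structure shared between genes.

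Gene lists for 32 cell types, pathways and technical signs were fixed before the data were examined, as were the tests, the main alternatives and the rule for named genes. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 32 lists. Calls within a list were also counted after adjustment over the list alone. Named genes were the 12 higher and 12 lower genes with the largest difference among called genes whose groups did not overlap, with free places filled by the smallest unadjusted p. They also included up to 4 members per list with the smallest p, Bst1 and 6 Paneth markers, and the 2 members of each cell type list with the highest mean. Genes outside this rule are said to be so.

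Alternatives were quantile normalization, median centring of arrays, no filter, a filter at the 60th percentile, the mean of all clusters per gene, eBayes without the trend or with robust estimation, array weights, an ordinary linear model, the replicate number as a block, and leaving out each array. Covariates for the leading residual component and for the enterocyte list mean were added after seeing the data. Figures were drawn with matplotlib (version 3.10.9).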

Results

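Gene expression was measured in sorted Paneth cells from calorie-restricted mice (4 arrays) and from mice fed ad libitum (3 arrays), to ask how the diet changes the cells that support the crypt's stem cells. Expression is given as the mean log2 value ± SD, with n = 4 for calorie restriction and n = 3 for ad libitum feeding, and differences are calorie restricted minus ad libitum ± SE. Array medians ranged from 7.24 to 7.44. Correlations between arrays, taken across genes, ranged from 0.949 to 0.993, and 0 pairs of arrays held identical values.

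Of 13409 genes tested, 88 were higher under calorie restriction and 1 was lower (limma, adjusted p below 0.05), and 56 of the 88 differed by at least 2-fold. The higher genes included 10 of 28 enterocyte (absorptive cell) markers, 7 of 39 genes of xenobiotic metabolism and 2 of 33 of fatty acid oxidation. These 3 lists passed the set test with a preset correlation, but not with an estimated correlation (adjusted p = 0.138, 0.0698 and 0.118). The largest difference was in Cyp3a11, a drug-metabolizing cytochrome P450, which was 6.65-fold higher (11.13 ± 0.54 against 8.39 ± 0.78, adjusted p = 0.0333). Its relative Cyp2c29 was at 8.49 ± 0.43 against 6.19 ± 0.21 (adjusted p = 0.00839). It was 1 of 9 higher genes with an ad libitum mean below the filter level of 6.79, where signal was not shown to exceed background, so the size of these differences is uncertain. Aldh1a1, which makes retinoic acid from retinal, rose by 2.01 ± 0.23 log2 units, and the aldo-keto reductase gene Akr1c19 by 2.04 ± 0.34. Transporters formed another part of this set. The dicarboxylate carrier Slc13a2 was 3.94-fold higher, the vitamin C carrier Slc23a1 was 3.67-fold higher, and the monocarboxylate carrier Slc5a12 was 3.67-fold higher. Ada, which deaminates adenosine, rose by 2.14 ± 0.35, and the ectonucleotidase gene Enpp3 by 1.86 ± 0.25. Cyp3a11 and Ada are also members of the enterocyte list. The remaining genes of the 12 were Susd2 (2.16 ± 0.21), Nat8f5 (2.07 ± 0.30) and Ly6m (2.04 ± 0.18).

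The groups did not overlap for any of the 89 called genes. Over all genes tested, 10.2% had groups that did not overlap, where chance gives 5.71% for independent arrays. The number of higher genes depended on single arrays. It was 12, 23, 12 and 58 without calorie restricted replicates 1, 2, 3 and 4, 32 without ad libitum replicate 2, and 96 and 97 without ad libitum replicates 1 and 3. Of the 88 genes, 12, 22, 12 and 51 were still called without calorie restricted replicates 1 to 4. Without ad libitum replicates 1 to 3 the numbers were 65, 31 and 58. All 88 kept their sign in these 7 fits, but groups that do not overlap make that certain, so it is no further support. With the mean of an enterocyte marker list as a covariate, added after seeing the data, limma called 0 genes. There 235 had an unadjusted p below 0.05, and 80 of the 88 kept their sign. That mean was 11.6 or more in every calorie-restricted array and 10.9 or less in every ad libitum array. Also, 10 of the 88 genes are in the list. The loss of calls therefore cannot tell diet from enterocyte content. An ordinary linear model in place of the moderated one called 0 genes, with 1318 at an unadjusted p below 0.05.

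The lower gene was Plagl1, an imprinted zinc finger transcription factor, at 7.35 ± 0.15 against 8.07 ± 0.11 (adjusted p = 0.0365). Its adjusted p rose to 0.121 after quantile normalization, to 0.106 after median centring, to 0.197 with the ordinary linear model and to 0.176 with the replicate block. It was between 0.0576 and 0.151 in 6 of the 7 fits without 1 array, the exception being the fit without ad libitum replicate 3 (0.0448), and from 0.00279 to 0.973 over all alternatives. The difference itself, -0.72 ± 0.11, stayed between -0.78 and -0.63 in the 18 alternatives that measured it, and was -0.69 ± 0.32 with the enterocyte covariate, where the error was larger. The count of lower genes was 2 without calorie restricted replicate 4, 9 without ad libitum replicate 1, and 0 without calorie restricted replicates 1, 2 or 3 or ad libitum replicate 2. The other 11 genes in the lower direction did not pass the threshold. The transcription factor Zbtb20 had a difference of -0.70 ± 0.14 (adjusted p = 0.0905), the dynein assembly factor Dnaaf3 -0.50 ± 0.09 (adjusted p = 0.0584), Ano7 -0.57 ± 0.13 and the adhesion receptor Adgrl2 -0.46 ± 0.10. With the mean of all clusters per gene, Adgrl2 was at -0.28 ± 0.09 (limma, adjusted p = 0.361). Wdr78, Chd6, Capn8, Ldlrad4, the dystrophin relative Utrn, the myosin Myo5c and Tdrd9 lay between -0.44 and -0.33.

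Bst1, an ectoenzyme that makes cyclic ADP ribose from NAD, is the gene for which this study is known, so its value here is not independent evidence. Its single transcript cluster (10521667) was 2.92-fold higher under calorie restriction, at 9.80 ± 0.36 against 8.25 ± 0.47 (limma, adjusted p = 0.0439). All 4 calorie-restricted arrays (9.27 or more) lay above all 3 ad libitum arrays (8.56 or less). The exact two-sided permutation test gave p = 0.0286, the smallest that 35 splits allow. The call was near the threshold. It ended with quantile normalization (adjusted p = 0.0676), the ordinary linear model (adjusted p = 0.245) and the replicate number as a block (adjusted p = 0.118). Adjusted p was 0.156, 0.140 and 0.144 without calorie restricted replicates 1, 2 and 3, and 0.0527, 0.130 and 0.0555 without ad libitum replicates 1, 2 and 3, while the difference stayed between 1.27 and 1.72. Enterocyte markers moved with the diets too, and with their mean as a covariate the difference was -0.13 (adjusted p = 0.973, against a lowest adjusted p of 0.00164 over the alternatives).

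No difference was detectable in 6 Paneth markers, whose 95% intervals included 0. The lysozyme gene Lyz1 was at 14.31 ± 0.04 against 14.31 ± 0.02 (95% interval of the difference -0.12 to 0.11), and the matrix metalloprotease Mmp7, which processes defensins, at 13.91 ± 0.15 against 13.96 ± 0.06 (-0.25 to 0.16). The niche ligands Wnt3 (-0.16 ± 0.29), Egf (0.08 ± 0.22) and Dll4 (-0.17 ± 0.17) and the sorting marker Cd24a (-0.04 ± 0.08) made up the rest. After median centring, which moved the median of all genes from 0.01 to 0.10, Lyz1, Mmp7 and Cd24a had differences of 0.08, 0.04 and 0.05. Values near 14 lie close to the top of the array's range, where differences may be compressed. Of 17 granule products measured, 0 passed over all genes or adjusted over the list alone. Mptx1, a mucosal pentraxin, had the smallest p, at 10.60 ± 0.79 against 12.02 ± 0.63 (adjusted p = 0.311), followed by Pnliprp2, Habp2 and Copz2 with differences from -0.25 to -0.11. The colipase gene Clps was among the brightest, at 14.23 ± 0.08 against 14.28 ± 0.07. Of 21 identity and niche genes 0 passed either count, and Mecom (-0.36 ± 0.17), Spdef (-0.33 ± 0.20), Fzd5 (0.29 ± 0.18) and Wnt11 (-0.11 ± 0.08) had the smallest p. Of the granule products 13 were negative and of the identity and niche genes 16, each list with a median of -0.05 (camera, adjusted p = 0.0686 and 0.0743, and adjusted p = 0.673 and 0.679 with an estimated correlation). After quantile normalization both lists passed in the lower direction (adjusted p = 0.0301 and 0.0214), and after median centring neither did (adjusted p = 0.110 and 0.0572) and both medians were 0.04.

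**Figure D1:**
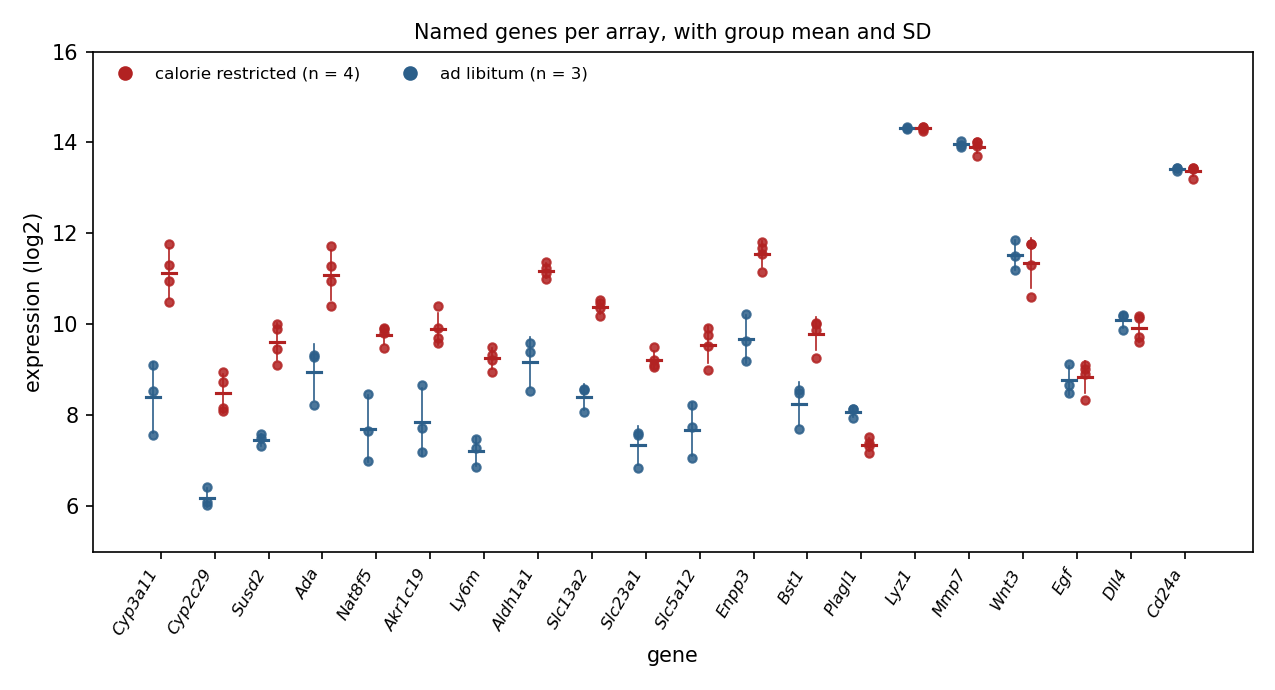
Expression (log2) of the 12 named higher genes, Bst1, the lower gene Plagl1 and 6 Paneth markers on each array, with points for arrays and lines for the group mean and SD (n = 4 calorie restricted, n = 3 ad libitum). Bst1 sits at 9.27 or more in calorie restriction and 8.56 or less in ad libitum feeding, while Lyz1 sits at 14.31 in both.

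Markers of enterocytes, the absorptive cells that a Paneth cell sort should leave out, were higher in the calorie-restricted arrays. Of 28 measured markers, 10 were higher over all genes tested, 23 were higher adjusted over the list alone, and the median difference was 1.03. The constitutive androstane receptor target Cyp2b10 was 3.45-fold higher (12.09 ± 0.18 against 10.31 ± 0.20, adjusted p = 0.00534). The apolipoprotein Apoc3 was 2.91-fold, the trehalase Treh 2.79-fold and the fatty acid binding protein Fabp2 2.09-fold higher. The brightest members had smaller differences: 0.34 ± 0.10 for the aminopeptidase Anpep, which did not pass over all genes (adjusted p = 0.264), and -0.02 ± 0.06 for Lypd8, both near the top of the range. The mean of the list was 11.8, 11.8, 11.8 and 11.6 in calorie restricted replicates 1 to 4 and 10.9, 10.3 and 10.9 in ad libitum replicates 1 to 3. The list passed the set test (camera, adjusted p = 5.75e-30), but not with an estimated correlation (adjusted p = 0.138).

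Lists that overlap with absorptive metabolism moved beside these markers. The glutathione, NRF2 and xenobiotic list had 7 of 39 members higher over all genes and 17 adjusted over the list alone, with a median difference of 0.43. It was led by Cyp2b10, Aldh1a1, Cyp2d26 and Cyp3a11 (camera, adjusted p = 8.72e-16, and adjusted p = 0.0698 with an estimated correlation), and with the enterocyte mean as a covariate its median was 0.15 (adjusted p = 0.0754). Fatty acid oxidation, ketogenesis and PPAR targets had 2 of 33 members higher over all genes and 16 adjusted over the list alone (adjusted p = 9.69e-16, and adjusted p = 0.118 with an estimated correlation), with a median of 0.31. With that covariate the median was 0.19 and the list kept its call (camera with the preset correlation, adjusted p = 0.00381). The enterocyte means of the diets do not overlap, so diet and enterocyte content cannot be told apart for this list. The fatty acid translocase Cd36 was at 7.79 ± 0.22 against 6.27 ± 0.22, the latter below the filter level, the transcription factor Creb3l3 was 2.49-fold higher, and Eci2 and Acot2 had differences of 0.76 ± 0.13 and 0.85 ± 0.15 without passing over all genes. The enterocyte list shared 2 members with the xenobiotic list and 1 with the fatty acid oxidation list, whose medians without them were 0.42 and 0.29. Other members may also be expressed in enterocytes, so this does not separate the lists from enterocyte content. In the fatty acid synthesis list, Dgat2, which makes triglyceride, was 2.20-fold higher. Dgat1 (0.58 ± 0.14), Agpat2 (0.45 ± 0.14) and Scd2 (-0.82 ± 0.26) did not pass over all genes, and the list did not pass (adjusted p = 0.301).

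Glucocorticoid response genes were also higher in the arrays with the higher enterocyte markers. Of 21 measured, 3 were higher over all genes and 10 adjusted over the list alone, with a median difference of 0.45. The transcription factor Zbtb16 was at 8.19 ± 0.10 against 7.06 ± 0.11 (adjusted p = 0.00799), the receptor co-chaperone Fkbp5 was 2.45-fold higher, and the kinase Sgk1 was 2.93-fold higher. The clock and glucocorticoid gene Per1 had a difference of 0.75 ± 0.13 (adjusted p = 0.0562). The list passed camera (adjusted p = 4.71e-11), with adjusted p = 0.0698 with an estimated correlation. With the enterocyte covariate its median was 0.32 and it kept its call (adjusted p = 0.0371), but that fit cannot tell diet from enterocyte content. The circadian clock list had 0 of 20 members past the threshold over all genes and 5 adjusted over the list alone (adjusted p = 9.15e-05, and adjusted p = 0.497 with an estimated correlation). Its median was 0.25, and 0.13 without ad libitum replicate 3. Ciart (1.40 ± 0.25), Cry2 (0.66 ± 0.13) and Usp2 (0.80 ± 0.16) followed Per1 there. FOXO targets had 0 of 32 past the threshold over all genes and 6 adjusted over the list alone (adjusted p = 0.0137, and adjusted p = 0.535 with an estimated correlation), and the list did not pass without ad libitum replicate 1 (adjusted p = 0.0562) or with the enterocyte covariate (adjusted p = 0.967). Its median was 0.11, and 0.20 after median centring. Their leading members were Gadd45b (0.62 ± 0.11), Cited2 (0.52 ± 0.10), the catalase gene Cat (0.42 ± 0.08) and the pyruvate dehydrogenase kinase Pdk4, which was 4.41-fold higher with adjusted p = 0.0891.

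The ATF4 and amino acid response list had a median of 0.26, with 35 of 37 members positive and 0 past the threshold by either count (camera, adjusted p = 1.65e-07, and adjusted p = 0.645 with an estimated correlation). With the enterocyte covariate the median was -0.11 (adjusted p = 0.0892). Its leading members were the transfer RNA ligase Iars (0.34 ± 0.08), the cationic amino acid carrier Slc7a1 (0.38 ± 0.10), the amino acid carrier subunit Slc3a2 (0.36 ± 0.10), and Trib3 (0.70 ± 0.19). Components of mTORC1, the growth kinase complex studied in this system, had a median of 0.09 and 0 of 39 members past the threshold by either count (adjusted p = 0.0915). Besides Slc3a2, Tbc1d7 (0.41 ± 0.11), Slc7a5 (0.58 ± 0.17) and Sesn3 (-0.34 ± 0.11) had the smallest p. Cytosolic ribosomal proteins had a median of 0.03 (54 members, adjusted p = 0.311), with Rps13 (0.17 ± 0.09), Rpl36a (0.11 ± 0.07), Rpsa (0.13 ± 0.09) and Rpl30 (-0.27 ± 0.19) leading. Ribosome biogenesis genes passed camera at a median of 0.09 (adjusted p = 0.0137, and adjusted p = 0.645 with an estimated correlation), led by Bop1 (0.26 ± 0.08), Pno1, Nhp2 and Wdr43. They did not pass without calorie restricted replicate 4 (median 0.06, adjusted p = 0.190) or ad libitum replicate 1 (0.05, adjusted p = 0.619), nor with the 60th percentile filter (adjusted p = 0.0754), array weights (0.04, adjusted p = 0.595) or the replicate block (0.06, adjusted p = 0.259). The median was 0.17 after median centring and 0.27 with the enterocyte covariate.

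Energy metabolism lists passed narrowly. Oxidative phosphorylation had a median of 0.07 with 62 of 71 members positive (adjusted p = 0.0461, and adjusted p = 0.753 with an estimated correlation), led by Ndufb8, Uqcr10, Ndufa11 and Cyc1, and 0 members passed over all genes. The list did not pass without calorie restricted replicate 1 (median 0.03, adjusted p = 0.629) or 4 (adjusted p = 0.312) or ad libitum replicate 1 (0.04, adjusted p = 0.605) or 2 (0.04, adjusted p = 0.417). Its median was 0.11 without calorie restricted replicate 3 (adjusted p = 9.03e-05) and 0.12 without ad libitum replicate 3 (adjusted p = 4.75e-05), and 0.15 after median centring. The call was also lost with the 60th percentile filter (adjusted p = 0.268), the mean of all clusters (adjusted p = 0.0518), no trend (adjusted p = 0.0688), array weights (adjusted p = 0.195), the replicate block (adjusted p = 0.285) and the enterocyte covariate (0.0122, adjusted p = 0.151). Glycolysis and glucose handling had 1 of 24 members higher (adjusted p = 0.0437, and adjusted p = 0.645 with an estimated correlation). That member was Fbp1, a gluconeogenic enzyme, 1.79-fold higher, ahead of Pkm (0.33 ± 0.10), Pfkl (0.28 ± 0.09) and Pfkfb3 (-0.47 ± 0.16). This list did not pass without calorie restricted replicates 1 or 4 (adjusted p = 0.118 and 0.161) or ad libitum replicates 1 or 2 (adjusted p = 0.0535 and 0.204), and its median of 0.08 was 0.16 without calorie restricted replicate 3, 0.18 without ad libitum replicate 3 and 0.17 after median centring. It kept its call in 5 of 18 alternatives, and the median was -0.0875 with the enterocyte covariate, where it did not pass. The NAD and cyclic ADP ribose list, which includes Bst1 and so is not independent of the study, had 2 of 21 members higher, Enpp3 and Bst1 (adjusted p = 0.0349, and adjusted p = 0.268 with an estimated correlation). Nampt (0.24 ± 0.08) and Nt5e (1.38 ± 0.57) did not pass, nor did the list without calorie restricted replicate 4 (adjusted p = 0.0873) or ad libitum replicate 1 (adjusted p = 0.130). The list kept its call in 9 of 18 alternatives, and its median of 0.07 was 0.15 after median centring, 0.04 with no filter and 0.14 with array weights (adjusted p = 0.209). Cholesterol synthesis genes were lower as a list, with 18 of 21 negative and a median of -0.11 (adjusted p = 0.00138, and adjusted p = 0.652 with an estimated correlation). Sqle (-0.33 ± 0.15), Hmgcs1, Msmo1 and Idi1 did not pass, nor did the list without ad libitum replicate 1 (median -0.05, adjusted p = 0.171) or with array weights (adjusted p = 0.118). The median was -0.02 after median centring and -0.33 with the enterocyte covariate. After quantile normalization the ribosome biogenesis, oxidative phosphorylation, glycolysis and NAD lists did not pass (adjusted p = 0.211, 0.659, 0.211 and 0.0840), and after median centring the NAD list did not (adjusted p = 0.0572).

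Lists for the remaining cell types moved less than the enterocyte list. Goblet markers had a median of -0.06, which was 0.03 after median centring, with 0 of 17 past the threshold by either count (adjusted p = 0.0260, and adjusted p = 0.652 with an estimated correlation). The list did not pass without calorie restricted replicate 4 (median -0.02, adjusted p = 0.312) or ad libitum replicate 1 (adjusted p = 0.389), nor with array weights (adjusted p = 0.775) or the replicate block (adjusted p = 0.305). The median was -0.46 with the enterocyte covariate. The mucin Muc2 was at 13.90 ± 0.06 against 14.10 ± 0.02 (adjusted p = 0.249), and Retnlb, Tpsg1 and Zg16 had differences of -1.32, -0.59 and 0.96. Tuft cell markers had a median of -0.10 with 15 of 16 negative (adjusted p = 0.0335, and adjusted p = 0.679 with an estimated correlation), and Plcb2 (-0.69 ± 0.26), Hpgds, Il25 and Alox5ap had the smallest p. The sign of the median depended on calorie restricted replicate 1, with a tuft median of 8.03 against 8.60 to 8.94 in the other arrays of its diet. Without that array the list's median difference was 0.04 and the list lost its call (camera, adjusted p = 0.897), though the direction of camera stayed negative. The list did not pass without ad libitum replicates 1 or 2 either (-0.08 and -0.01, adjusted p = 0.111 and 0.254), and its median was -0.28, -0.17 and -0.28 without calorie restricted replicates 2 and 4 and ad libitum replicate 3. It was -0.01 after median centring, -0.17 with the replicate block and 0.64 with the enterocyte covariate, and the call was lost with no filter (adjusted p = 0.0626) and with array weights (-0.16, adjusted p = 0.115). Enteroendocrine markers had a median of 0.21 with 23 of 25 positive (adjusted p = 0.0686), led by Gcg (0.28 ± 0.10), Cck (0.30 ± 0.12), Pax6 and Ghrl. Their medians spread widely, from 8.84 to 10.2 within the calorie-restricted arrays. The immune list (median -0.04, adjusted p = 0.802) and the stromal list (-0.08, adjusted p = 0.0711) had 0 members past the threshold, and their medians were 0.05 and 0.01 after quantile normalization. In the crypt stem cell list, 1 of 21 members was higher, Clca4a (10.28 ± 0.09 against 9.40 ± 0.13, adjusted p = 0.0106), and Igfbp4 (0.62 ± 0.17), Prom1 and Lrig1 did not pass. The list itself had a median of 0.01, which was -0.02 after quantile normalization, and an adjusted p of 0.819. Pancreatic acinar genes had 0 of 13 past the threshold over all genes and 2 adjusted over the list alone, with Reg3a at 1.30 ± 0.33 and Spink1 at 0.87 ± 0.22 (adjusted p = 0.258 for the list).

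**Figure D2:**
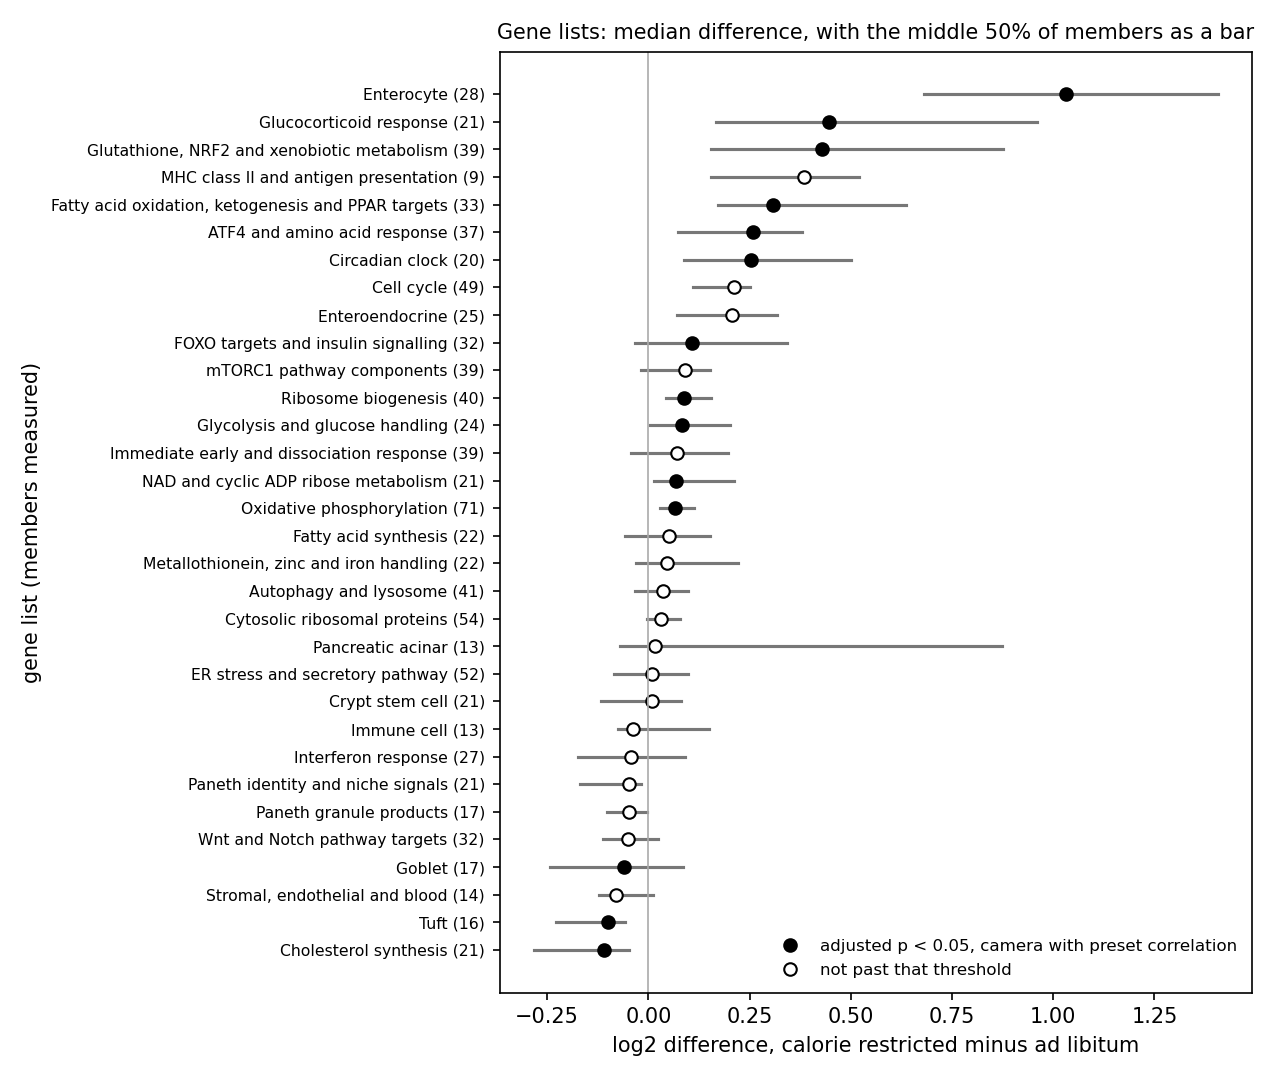
Median log2 difference, calorie restricted minus ad libitum, of each of 32 gene lists, with bars for the middle 50% of members and the number of measured members in brackets. Filled points passed camera with a preset correlation. The enterocyte list lies highest at 1.03 and the cholesterol synthesis list lowest at -0.11.

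The other lists did not pass the set test. They were cell cycle (median 0.21, adjusted p = 0.0686), ER stress and secretory pathway (0.01, adjusted p = 0.629), autophagy and lysosome (0.04, adjusted p = 0.896), immediate early and dissociation response (0.07, adjusted p = 0.129), interferon response (-0.04, adjusted p = 0.113), MHC class II and antigen presentation (0.39, adjusted p = 0.113), Wnt and Notch pathway targets (-0.05, adjusted p = 0.114) and metallothionein, zinc and iron handling (0.05, adjusted p = 0.144). After quantile normalization the ER and Wnt and Notch lists passed in the lower direction, with medians of -0.03 and -0.06 (adjusted p = 0.0400 and 0.0348). After median centring the interferon and the Wnt and Notch lists had medians of 0.04. Within the 8 lists, adjusted over the list alone, 1 immediate early gene (Gadd45b) and 2 metal handling genes (Slc30a10 at 0.63 ± 0.14 and Heph at 0.42 ± 0.10) were higher. For the ER and crypt stem cell lists the median was positive and the direction of camera negative. For the ER, immune and crypt stem cell lists the mean was positive and the direction of camera negative. In all, 14 of 32 lists passed camera with the preset correlation, and 0 passed with an estimated correlation (lowest adjusted p = 0.0698). Another 5 results came from fry, which tests a list by itself without comparing it with other genes. The lists past fry were glucocorticoid (fry, adjusted p = 0.00471), xenobiotic (adjusted p = 0.00716), NAD (adjusted p = 0.00734), enterocyte and fatty acid oxidation (both adjusted p = 0.0103). These 5 were also among the 14. Members of 1 list are not independent of each other. With the preset correlation, every other split of the arrays into 4 and 3 also passed 7 or more lists. A pass there is weak evidence for a list.

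The arrays differed in a way the diets did not explain. The first principal component of the genes tested held 48.7% of the variance. Calorie restricted replicate 4 and ad libitum replicates 2 and 3 scored 22.7, 13.4 and 19.6 on it, calorie restricted replicates 2 and 3 and ad libitum replicate 1 scored -14.9, -16.6 and -24.5, and calorie restricted replicate 1 scored 0.296. The second component held 27.6% and separated the diets, with scores from 9.33 to 13.6 in calorie restriction and from -19.2 to -6.98 in ad libitum feeding. No slide, date or batch label was used here. With the leading component of the spread within diets as a covariate, chosen after seeing the data, 573 genes were higher and 118 lower, and these included all 88. Bst1 then had an adjusted p of 0.00404. The component comes from the same values, so these p-values are too small.

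**Figure D3:**
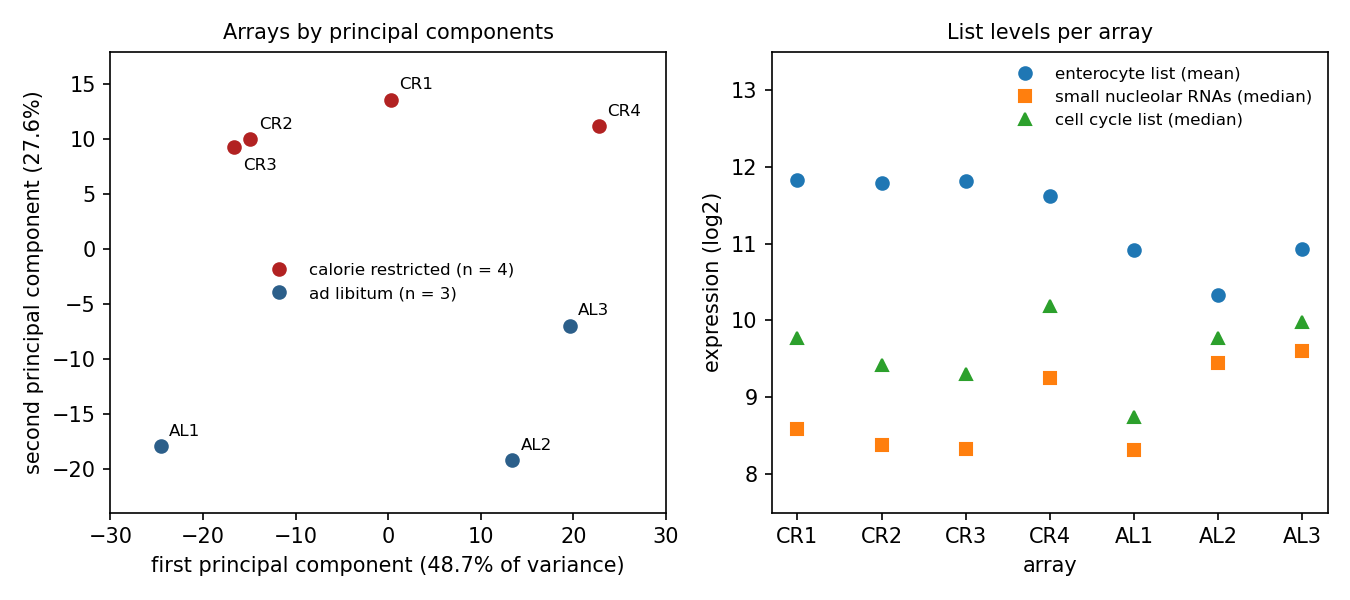
Left, scores of the 7 arrays on the principal components of the genes tested (CR, calorie restricted; AL, ad libitum; number, replicate). Right, expression (log2) of the enterocyte list, small nucleolar RNAs and cell cycle list on each array. Enterocyte means are 11.6 or more in calorie restriction and 10.9 or less in ad libitum feeding.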

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

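The reading of quantile normalization in this part was chosen only after the results were seen. Of 63 results tested in the 4 calorie-restricted arrays for a sample far from the others, 2 stood out, where chance alone would give about 3.15. The sorting marker Cd24a was at 13.20 in calorie restricted replicate 4 and between 13.42 and 13.44 in the other arrays of the group, a gap of 0.882 of the group's range. The median of the ER stress and secretory pathway list was 11.43 in the same array and between 11.80 and 11.87 in the others, a gap of 0.832 of the range.

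The same array had a high score on the component that crosses the diets. Calorie restricted replicate 4 and ad libitum replicates 2 and 3, the high scorers, also had the highest array medians (7.42, 7.44 and 7.42). The other medians were 7.24 to 7.29. The ER list's median was also lower in ad libitum replicates 2 and 3 (11.61 and 11.54) than in ad libitum replicate 1 (11.99). Its low level was thus not particular to calorie restricted replicate 4. The first component held 51.8% of the variance after quantile normalization and 48.7% before. Whether the arrays kept their scores was not checked, so these shares do not decide on scaling between arrays. On the leading component of the spread within diets, 46 small nucleolar RNAs, picked after they were seen, had a median loading of 1.40 and 49 cell cycle genes one of 1.07. The small nucleolar RNAs also had a median difference between the diets of -0.35, which was not tested as a list, and their array medians overlapped, from 8.33 to 9.25 in calorie restriction and from 8.31 to 9.61 in ad libitum feeding. Scaling between arrays, a share of cycling cells, RNA handling and differences between animals stay open.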

How the results depend on the processing

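The covariates were chosen after seeing the data. With 88 genes higher, 1 lower and Bst1 at 1.54 at first, quantile normalization gave 53 higher and 0 lower with Bst1 at 1.55 (adjusted p = 0.0676), median centring 0 lower with Lyz1 at 0.0832, Mmp7 at 0.0391 and Cd24a at 0.0473, the 60th percentile filter 0 lower, no filter 2 lower, and array weights 963 higher and 392 lower with Lyz1 at 0.0119, Mmp7 at 0.0313, Wnt3 at 0.117 and Cd24a at 0.0306. Median centring shifted the median difference of all genes to 0.10 from 0.01. The ordinary linear model called 0 higher and 0 lower genes, with 1318 at an unadjusted p below 0.05, and left Bst1 at 1.54 with an adjusted p of 0.245, since it shares no spread between genes. With the replicate block, limma called 0 higher and 0 lower genes, with 988 at an unadjusted p below 0.05, and Bst1 was at 1.72 (adjusted p = 0.118), Lyz1 at 0.0119, Mmp7 at 0.0241, Wnt3 at 0.0895 and Cd24a at 0.0196. Calorie restricted replicate 4 has no partner in that fit and drops out of the diet difference, so these differences equal those without it, and fewer residual degrees of freedom are left. Deviations from the group means gave no sign that equal replicate numbers pair the arrays. They correlated across genes at -0.13, -0.27 and -0.55 for numbers 1 to 3. None of these 3 calorie-restricted arrays correlated best with the ad libitum array of its number. The leading component of the spread within diets held 65.7% of these deviations. The correlations can largely reflect that component, so they cannot exclude pairing. The residual component covariate gave 573 higher and 118 lower, with p-values too small since the component comes from the same values. The enterocyte mean covariate gave 0 higher and 0 lower (limma, 235 at an unadjusted p below 0.05), Bst1 at -0.13, Slc5a12 at -0.0546 and Egf at -0.487. The lists then had medians of -0.0617 (enterocyte), 0.64 (tuft), -0.11 (ATF4), 0.0122 (oxidative phosphorylation) and -0.0875 (glycolysis). The enterocyte value says nothing, since the covariate is the mean of that same list and so removes its average difference. Without 1 array, counts ranged from 12 to 97 higher and from 0 to 9 lower, and Bst1 from 1.27 to 1.72, Lyz1 from -0.0147 to 0.0119, Mmp7 from -0.0842 to 0.0241, Wnt3 from -0.328 to 0.0895, Egf from -0.0568 to 0.255 and Cd24a from -0.0626 to 0.0196. The cause of these changes was otherwise not tested.

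The number of lists past the set test stayed between 11 and 19 except with an estimated correlation, where it was 0. These were not always the same lists. Of the 14, 6 were still called without ad libitum replicate 1, 7 with array weights, and 7 with the enterocyte covariate, of which the tuft list in the other direction. With quantile normalization 10 of the 14 were still called, and lists split into 7 higher and 7 lower, against 11 and 3 at first. Over other named genes, 433 of 565 values under alternatives kept direction and side of the threshold, 88 lost the call, 23 gained it and 21 changed sign, of which 20 were of Paneth markers that did not pass at first and 1 of Slc5a12. Over the 14 lists that passed, by the direction of the set test and not of the median, 184 of 252 values kept direction and call, 63 lost the call and 5 reversed. The 5 include the enterocyte list with its own mean as covariate, a circular setting. The median changed sign in 7 of the 252, and for oxidative phosphorylation the set test reversed while the median stayed positive. The pseudocount and the suffix-based probe choice were not run, since values were on a log scale and cluster identifiers carry no suffix. Camera has no robust or ordinary form, so those settings give no list values. Signal over background is unknown here, which limits what can be said of dim genes.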

Other observations

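The tests in this part, apart from the fit with quantile normalization and the set test, were chosen only after the results were seen. Of the 88 higher genes, 25 belonged to one of the fixed lists and 63 to none. Solute carrier genes made up 10 of the 88 (11.4%) and 1.86% of the genes tested, an odds ratio of 6.98 (Fisher's exact test across genes, adjusted p = 5.34e-06 over 2 families). Cytochrome P450 genes made up 9 of the 88 (10.2%) and 0.268% of the genes tested, an odds ratio of 55.9 (adjusted p = 2.42e-12). Genes are not independent replicates, and the families were picked after their members were seen. The solute carriers outside the naming rule included Slc6a19, a neutral amino acid carrier (1.65), and Slc27a4, a fatty acid carrier (0.94). Among the P450 genes outside it were Cyp4b1 (1.32) and Cyp2d22 (1.05).

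MHC class II and antigen presentation genes differed between arrays more than between diets. Their median was 9.56, 10.0, 9.57 and 10.7 in calorie restricted replicates 1 to 4 and 8.85, 10.3 and 9.37 in ad libitum replicates 1 to 3. Probe sets with no single gene symbol gave 0 higher and 0 lower of 6694 tested (limma), with 160 higher and 180 lower at an unadjusted p below 0.05.

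The enterocyte signal is the pattern with most bearing on the rest. Scaling between arrays is argued against, since the list's median was 1.01 after quantile normalization. A loss of Paneth cells that raised all other cell types alike is too. Enterocyte markers exceeded those of goblet, enteroendocrine, tuft, immune and stromal cells by 1.06 (bootstrap interval 0.808 to 1.29). A loss of Paneth cells made up mainly by enterocytes would leave the same gap, so that stays open. A larger share of enterocytes in the calorie-restricted sorts may explain the enterocyte signal. Markers that differed more between the diets also followed the others more from array to array within the diets. The rank correlation across the 28 markers, of which 3 are in another list, was 0.732 (interval 0.413 to 0.905). Genes are not independent replicates, and genes with a wide range would do the same if the diet changed them within Paneth cells, so that effect of the diet, which was not tested, stays open. The spread within the diets also leaned on ad libitum replicate 2, whose list mean was 10.3 against 10.9 in replicates 1 and 3. An interval over genes does not reflect that dependence on a single array. The sort should remove enterocytes. The most abundant markers, Lypd8 (13.80 against 13.82) and Anpep (13.48 against 13.15), lie near the top of the range. Differences may be compressed there, which was not tested. Fabp2 reached 13.19 in calorie restriction and still differed by 1.06. The small differences of Lypd8 and Anpep therefore do not favour a larger share of enterocytes, but these markers alone cannot decide against it.

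The same share could bear on Bst1 and on the glucocorticoid genes. With the enterocyte mean as a covariate the diet difference of Bst1 was -0.13 (95% interval -1.06 to 0.80), but the enterocyte means of the diets do not overlap, so diet and enterocyte content cannot be told apart for Bst1. For the mean of the glucocorticoid list the diet difference was 0.61 without and 0.38 with this covariate (95% interval -0.12 to 0.88). The list still passed camera with this covariate, at a median of 0.32 (adjusted p = 0.0371), but diet and enterocyte content cannot be told apart there for the same reason.

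Other splits of the 7 arrays bear on the counts. Of the 35 splits into 4 and 3, 3 gave as many higher genes as the 88 of the diets, 3 gave as many lower genes as the 1, and 3 gave as many in both directions as the 89, with up to 1029, 569 and 1598 in another split. Chance can therefore not be excluded for these counts by this test. The split with 1598 set calorie restricted replicates 1, 2 and 3 and ad libitum replicate 1 apart, and one with 945 set calorie restricted replicates 2 and 3 and ad libitum replicate 1 apart, which points to the structure of the arrays on the leading component. No further split gave more than 1 gene. With the residual component as a covariate the diets gave 573 higher and 118 lower genes. That component is drawn from the same values after the diet means are removed, so it narrows the error and leaves the differences unchanged. It was not applied to the other splits, so these counts do not bear on chance. For the gene lists, 17 of the 35 splits gave as many as the 14 of the diets, with up to 19, so chance cannot be excluded for the number of lists. The lowest number in any split was 7. Passing camera with the preset correlation therefore does not by itself set the diets apart from other groupings of these arrays.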
